A study of Rattus norvegicus with 6 samples.

How the data were processed

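Gene expression was measured by RNA-seq in 6 libraries of RBL-2H3 cells, 3 control and 3 given PIO, the PPARγ agonist of the series, at 10 µM for 6 h. Per the labels' protocols, RNA was extracted with TRIzol and made into libraries with a stranded mRNA kit of Illumina. The deposited values are FPKM per gene and library, made by the authors, that is fragments scaled to gene length in kilobases and to the reads of the library. Per the submitters' processing notes, the tools were Trimmomatic 0.36, FastQC 0.11.5, HISAT2 2.2.1.0, BWA 0.7.5a, SAMtools 1.3.1, Cufflinks, HTSeq and DESeq. Which of them aligned or counted the reads is not given in the sources used here. Per the same notes the genome build was GRCh38, a human build, while the gene names and identifiers in the deposited table are those of the rat. The build behind the values is therefore unclear, and no coordinates are printed.

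The deposited table lists 22601 genes, 7172 of them at 0 in every library. Gene symbols that a spreadsheet had turned into dates (27) were restored through the GeneID. Of the GeneIDs, 20633 (91.3%) matched the RefSeq gene table of the rat assembly GRCr8, which was used for names only. FPKM values of a gene were whole multiples of the value of 1 read, so the reads behind them were recovered. Whole reads (tolerance 1e-04 of a read) and a whole gene length were found for 15428 genes, 99.99% of those above 0. The tolerance for a length was 0.02 bases and widened with the multiple of the read numbers tried, up to 12, and 15237 genes needed no multiple. The recovered reads summed to 13980244 to 15012210 per library, 99.5% of the total that scaled the FPKM. They give the depth, a floor of 3 reads for a gene listed at 0, and gene lengths. Floors cover counting error only, because the reads carry no molecular identifiers.

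Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with group as the only term, a variance trend with the mean, two-sided tests and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. Members of a list were also adjusted over the list alone. That second adjustment does not cover the number of lists, so some members can pass it by chance. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so no single gene was tested that way. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

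The groups, the test, the rule for named genes, the 34 lists and the alternatives, except those named below as added, were chosen before the data were examined. The rule names genes with an established symbol. It takes the genes with the most extreme log2 fold changes past the threshold or, with fewer than 5 genes past it, the 5 with the smallest p in each direction. It also takes a fixed set of PPAR, lipid, IgE receptor and cytokine genes and up to 4 members of each list with the smallest p. The lists were PPAR targets, fatty acid oxidation, PPAR receptors and partners, cholesterol genes, fatty acid synthesis, and LXR targets. For the cell type they were mast cell and basophil genes, FceRI signalling, granule exocytosis, eicosanoid synthesis, and cytokines and chemokines. For signalling, stress and metabolism they were NF-kB responsive genes, immediate early genes, NRF2 antioxidant genes, the integrated stress response, the unfolded protein response, glycolysis and hypoxia, and nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. The rest were S phase, G2 and M phase, p53 targets, interferon-stimulated genes, heat shock, lysosome and autophagy, ribosomal proteins, and the circadian clock. Markers were taken of macrophages, neutrophils, eosinophils, T and NK cells, B cells, erythroid cells and megakaryocytes, and fibroblasts and adipocytes. Mitochondrially encoded genes were not analysed here.

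The alternatives were pseudocounts of 0.1 and 1, no filter and minimum means of 1 and 5 FPKM, median-of-ratios, quantile and TPM scaling, no variance trend, a robust variance fit, sample weights, the replicate number as a block, each library left out in turn, and for the lists an estimated correlation and fry. After the data were seen, limma-voom on the recovered reads and a correction for gene length were added. The correction subtracts each library's lowess trend with log2 gene length, taken relative to the mean over libraries. Replicate numbers are shared between the groups, and whether they pair the libraries was checked before the fits were compared. The code was tested on simulated data of 10410 genes for PIO against control, with 200 genes changed and a dispersion of 0.00149 for every gene. It recovered 36% of the genes changed 1.2-fold, 92% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 13 unchanged genes called. The changed genes were drawn only from genes with more reads, so these shares do not cover genes with few reads. In the real data the variance differed more from gene to gene (limma prior degrees of freedom 4.22), so these shares are likely too high for the real genes. With no gene changed it called 0 genes and 0 lists. The simulated genes varied independently of each other. This result therefore does not show how the list test behaves when members of a list vary together.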

Results

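RBL-2H3 is a rat basophilic leukemia line that is widely used as a model of mast cells and basophils, because it carries the high-affinity IgE receptor and releases granules when that receptor is crosslinked. PPARγ is a nuclear receptor that is activated by ligands and is best known as a regulator of adipocyte and lipid genes. The series asked how a PPARγ agonist changes gene expression in this line. It compared 3 control libraries with 3 libraries from cells given PIO, the PPARγ agonist of the series, at 10 µM for 6 h. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No vehicle or time is recorded here for the control libraries, so a difference in either cannot be told apart from PIO. The deposited table lists 22601 genes in FPKM, of which 15429 were above 0 in at least 1 library. The FPKM values resolved into whole reads. The library totals behind them were 15084729, 14105533 and 14780606 reads in control replicates 1 to 3 and 14048202, 14322720 and 14084908 reads in PIO replicates 1 to 3. Between 9824 and 9876 genes per library had at least 1 FPKM, and the 10 most abundant genes held 6.40% to 6.61% of the total FPKM. Pearson correlations of log2 values between libraries, taken across genes, lay between 0.992 and 0.996. All pairs of libraries differed by more than counting noise, with overdispersion factors of 2.73 to 8.60. The libraries did not separate by group on these measures. Control replicate 1 lay closer to PIO replicate 1 (correlation 0.9953, factor 2.73) than to control replicate 3 (0.9936 and 6.10). Control replicate 2 also lay closer to PIO replicate 1 (0.9950 and 3.15) than to control replicate 3 (0.9938 and 5.57).

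Cpt1a (GeneID 25757) encodes the carnitine palmitoyltransferase that controls the entry of long-chain fatty acids into mitochondria. It went from 6.05 ± 0.388 FPKM in control to 12.5 ± 0.204 FPKM with PIO (SD, n = 3 per group), a fold of 2.07. Hmox1 (GeneID 24451) encodes the inducible heme oxygenase that degrades heme. It went from 155 ± 1.84 FPKM in control to 194 ± 4.71 FPKM with PIO (SD, n = 3), an increase of 24.8%. Of 10410 genes tested, 4 changed and all 4 rose, with every PIO value above every control value. The log2 fold change on the log2(FPKM + 0.5) scale was 0.99 (SE 0.06, adjusted p = 0.00159, limma with Benjamini-Hochberg adjustment) for Cpt1a and 0.32 (SE 0.03, adjusted p = 0.026) for Hmox1. Cpt1a had 417, 429 and 399 recovered reads in the control libraries and 838, 827 and 828 with PIO. The Hmox1 call was lost when any 1 library was left out, with limma adjusted p between 0.0562 and 0.148 and log2 fold changes between 0.30 and 0.34. It was also lost without a filter on low values (limma adjusted p = 0.0796), without a variance trend (limma adjusted p = 0.214) and with the replicate number as a block.

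The other 2 genes that rose carry placeholder symbols, fall outside the rule for named genes, and were chosen after their values were seen. LOC100912534, annotated as similar to an RNA polymerase subunit, went from 2.73 ± 0.494 to 9.86 ± 1.02 FPKM (SD, n = 3), with a log2 fold change of 1.69 (limma adjusted p = 0.00239). LOC102556337, annotated as similar to mitochondrial fission factor, went from 1.47 ± 0.349 to 5.87 ± 1.3 FPKM (SD, n = 3), with a log2 fold change of 1.69 (limma adjusted p = 0.026). Both are uncertain, because reads can be shared with related copies. Polr2h, the named gene related to LOC100912534, was listed at 0 in all 6 libraries although every cell uses its product, so a value of 0 in this table can be a failed assignment of reads. The call of LOC102556337 was lost without control replicate 2, control replicate 3, PIO replicate 1 or PIO replicate 2 (limma adjusted p = 0.0953, 0.0612, 0.0825 and 0.148). Without a filter neither was called (limma adjusted p = 0.0529 for LOC100912534 and 0.221 for LOC102556337), and without a variance trend LOC102556337 was not (0.127).

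**Figure D1:**
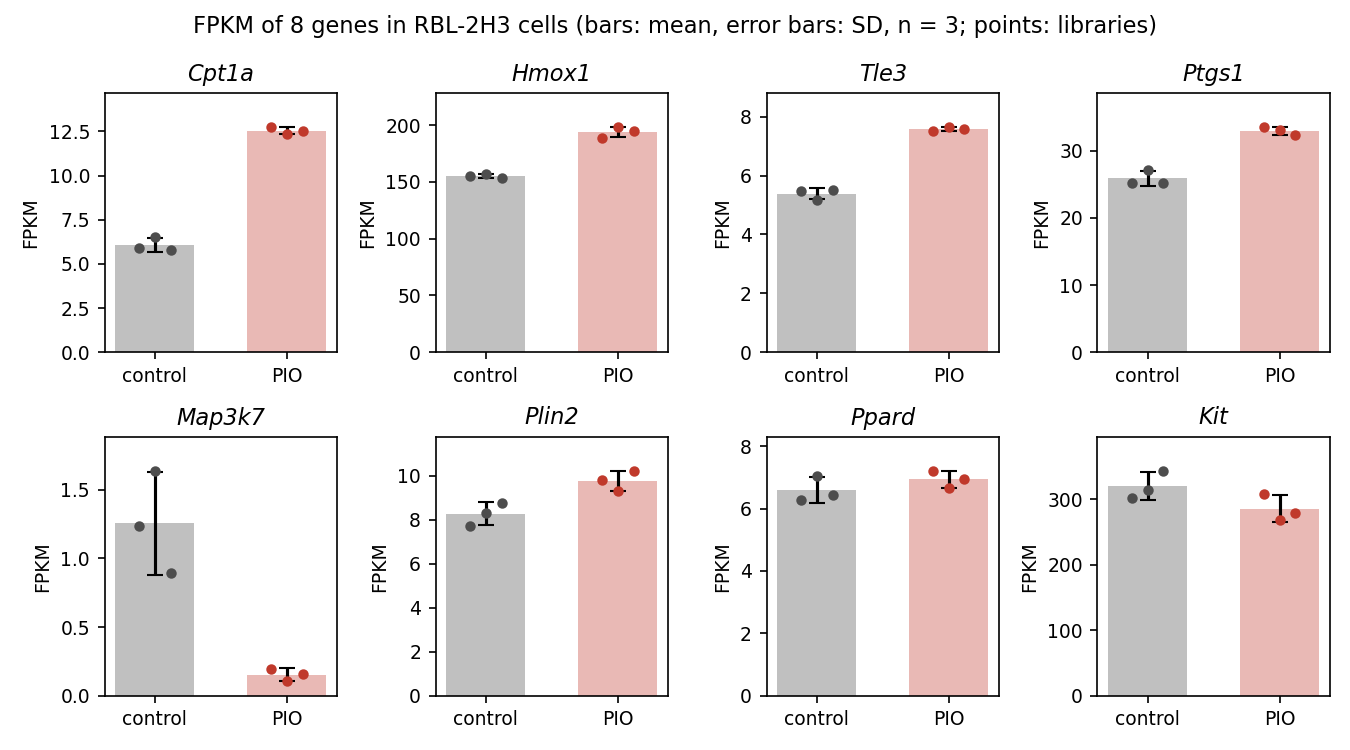
FPKM of 8 genes in control and PIO libraries of RBL-2H3 cells, with bars for group means, error bars for SD (n = 3) and 1 point per library; each vertical axis starts at 0. Cpt1a and Hmox1 passed the threshold over all genes tested, while Tle3, Ptgs1, Map3k7, Plin2, Ppard and Kit did not.

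No gene fell past the threshold in the limma test, whereas limma-voom on the recovered reads called 7 genes, 6 higher and 1 lower. At an unadjusted p under 0.05, 1302 genes (12.5%) stood out, 662 higher and 640 lower. The control and PIO values did not overlap for 1931 genes (18.5%, against 10% by chance with 3 against 3). In the other splits of the 6 libraries into 3 and 3, 186 to 1000 genes had an unadjusted limma p under 0.05. The split with 1000 set control replicate 1 and PIO replicates 2 and 3 against the rest. A high count of this kind therefore need not come from PIO. Because fewer than 5 genes passed, the 5 genes with the smallest p in each direction are given, most of them as not passing. Beside Cpt1a and Hmox1, the higher ones were Tle3, Ptgs1 and Lmna. Tle3 encodes a Groucho-family corepressor (5.38 ± 0.184 to 7.58 ± 0.0612 FPKM, SD, n = 3; log2 fold change 0.46, limma adjusted p = 0.0726). Ptgs1 encodes the constitutive cyclooxygenase (25.9 ± 1.13 to 33.0 ± 0.574 FPKM; 0.34, limma adjusted p = 0.073). Lmna encodes nuclear lamins A and C (0.25, limma adjusted p = 0.16). The lower ones were Map3k7, which encodes the kinase TAK1 (1.25 ± 0.373 to 0.154 ± 0.0461 FPKM; -1.40, limma adjusted p = 0.0697), Lrrc58 (-0.70, adjusted p = 0.16), the heme synthesis enzyme gene Cpox (-0.24, adjusted p = 0.21), Mid1ip1 (-0.26, adjusted p = 0.21) and F2rl2, a protease-activated receptor gene (-0.26, adjusted p = 0.21). Some settings passed 3 of these genes. Limma-voom on the recovered reads passed Tle3 (adjusted p = 0.00909), Ptgs1 (adjusted p = 0.0305) and Map3k7 (adjusted p = 0.0135), and so did the robust limma fit (adjusted p = 0.04998, 0.04998 and 0.0261). Limma with sample weights passed Tle3 (adjusted p = 0.0374) and Map3k7 (adjusted p = 0.0169). Map3k7 also passed in limma with a pseudocount of 0.1 (-2.39, adjusted p = 0.0404) and without control replicate 3 (-1.56, adjusted p = 0.0407). None of the 3 passed without a filter (limma adjusted p = 0.262, 0.221 and 0.221 for Tle3, Ptgs1 and Map3k7) or without a variance trend (0.0746, 0.281 and 0.127).

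Known PPAR target genes were higher as a list. Of its 40 genes, 19 were abundant enough to test. Of these 19 tested members 14 were higher and 5 lower, with a median log2 fold change of 0.10 (camera adjusted p = 0.00581). The list was not called with an estimated correlation (adjusted p = 0.601 with an estimated correlation). Over all genes tested 1 member rose, and adjusted over the list alone 5 rose, 1 fell and 13 did not pass. The 5 included Cpt1a and the lipid droplet genes Hilpda (10.9 ± 1.17 to 13.6 ± 0.226 FPKM, SD, n = 3) and Plin2 (8.27 ± 0.523 to 9.77 ± 0.471 FPKM). The others were the lipase gene Mgll (6.04 ± 0.159 to 7.07 ± 0.157 FPKM) and the thiolase gene Acaa2 (25.6 ± 1.06 to 29.2 ± 1.46 FPKM). The 1 that fell was the transcription factor gene Klf9 (1.46 ± 0.278 to 0.856 ± 0.218 FPKM). The list's median was 0.059 without PIO replicate 2 and 0.068 without PIO replicate 3, and its call was kept in both. Without a filter on low values the median was 0.051 and the call was lost (camera adjusted p = 0.055), and fry did not call the list (adjusted p = 0.1). Several well-known targets had too few reads for a fold change, and those named next were not detected in any PIO library. A value of 0 can also be a failed assignment of reads. Pdk4, Fabp4 and Cd36 were listed at 0 in all 6 libraries. Angptl4 had 1 recovered read in each control library and 0 in each PIO library, below the floor of 3 reads. Fabp5, the fatty acid binding protein gene that was well measured, stood at 125 ± 15.8 and 129 ± 0.623 FPKM (SD, n = 3; log2 fold change 0.06, limma adjusted p = 0.773), and without control replicate 3 its sign turned (-0.046).

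Fatty acid oxidation genes were the most uniform of the lipid lists, with 26 of 27 tested members higher. The median log2 fold change was 0.08 (camera adjusted p = 1.71e-06), with adjusted p = 0.366 with an estimated correlation and 0.0344 by fry, which asks whether the members move on balance 1 way. Adjusted over the list alone, Cpt1a and Etfb, an electron transfer flavoprotein subunit gene (229 ± 7.75 to 254 ± 4.25 FPKM, SD, n = 3), rose and 25 members did not pass. Acaa2, which is in both lists and passed over the PPAR target list alone, was among these 25. Over all genes tested only Cpt1a rose. Without Cpt1a the median was 0.078 (camera adjusted p = 2.43e-05), and under TPM scaling with all members it was 0.055 (camera adjusted p = 1.38e-06). Fatty acid synthesis genes were lower as a list, with 11 of 17 lower and a median of -0.06 (camera adjusted p = 0.0232; adjusted p = 0.64 with an estimated correlation). No member changed over all genes tested, and adjusted over the list alone 3 fell and 14 did not pass. The 3 were the stearoyl-CoA desaturase genes Scd2 (253 ± 8.51 to 213 ± 15.4 FPKM, SD, n = 3) and Scd (46.5 ± 0.944 to 39.3 ± 3.31 FPKM) and the ATP citrate lyase gene Acly (227 ± 1.91 to 207 ± 7.80 FPKM). That call was lost without control replicate 1 (median -0.057, adjusted p = 0.164) or PIO replicate 3 (-0.022, adjusted p = 0.0657), and the median was -0.028 without control replicate 2. It was also lost after the correction for gene length (-0.032, adjusted p = 0.0712), in a list with a median length of 4327 bases, without a variance trend (adjusted p = 0.0591) and by fry (adjusted p = 0.351). Cholesterol genes were not called (10 of 23 higher, median -0.0089, camera adjusted p = 0.113). They were called without control replicate 2 (-0.039, adjusted p = 0.0177), control replicate 3 (-0.021, adjusted p = 0.0431) or PIO replicate 2 (-0.036, adjusted p = 0.0399), while the median turned positive without control replicate 1 (0.0039) or PIO replicate 3 (0.0075). It was -0.037 under TPM scaling (adjusted p = 0.0644), -0.025 under quantile normalization (adjusted p = 0.112), -0.027 after the length correction (adjusted p = 0.0712) and -9.8e-05 with sample weights (adjusted p = 0.198). LXR targets and cholesterol efflux genes were not called (7 of 11 higher, median 0.05, adjusted p = 0.725). Their median was 0.011 without control replicate 2, 0.0036 without a filter, 0.017 under TPM scaling and 0.016 after the length correction. No member of the cholesterol and LXR lists passed, including adjusted over the list alone.

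The receptors themselves differed widely in the reads recovered for them. Ppard was well measured at 6.59 ± 0.411 FPKM in control and 6.94 ± 0.278 FPKM with PIO (SD, n = 3; log2 fold change 0.07, limma adjusted p = 0.67). Pparg had 1, 0 and 1 recovered reads in control replicates 1 to 3 and 0 in each PIO library, and Ppara had 0, 1 and 1 and then 0 in each, so neither could be compared. Rxra, the partner receptor gene, stood at 1.27 ± 0.0676 and 0.838 ± 0.0566 FPKM (-0.41, limma adjusted p = 0.29). Of 14 tested receptors, partners and coregulators 3 were higher and 11 lower. The median was -0.06 (camera adjusted p = 0.113) and none passed, including adjusted over the list alone. The list was called without PIO replicate 1 (-0.067, adjusted p = 0.0418). In the other direction, its median was -0.025 after the correction for gene length (adjusted p = 0.523), in a list with a median length of 7169.5 bases, and -0.032 at a minimum mean of 5 FPKM (adjusted p = 0.524).

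Antioxidant genes known as targets of the transcription factor NRF2 were higher as a list, with 19 of 23 higher and a median log2 fold change of 0.06 (camera adjusted p = 0.00123). The list was not called with an estimated correlation (adjusted p = 0.366 with an estimated correlation) and was called by fry (adjusted p = 0.0111). Its median length was 1547 bases, and its median log2 fold change was 0.037 after the correction for gene length (camera adjusted p = 0.0277) and 0.03 under TPM scaling (camera adjusted p = 0.00164). Over all genes tested only Hmox1 rose, and adjusted over the list alone 4 rose and 19 did not pass. Beside Hmox1 these were the sulfiredoxin gene Srxn1 (14.7 ± 0.561 to 18.0 ± 1.23 FPKM, SD, n = 3), the ferritin light chain gene Ftl1 (849 ± 39.3 to 964 ± 43.2 FPKM) and the quinone reductase gene Nqo1 (622 ± 23.2 to 689 ± 18.3 FPKM). The cystine transporter gene Slc7a11 was lower, at 2.33 ± 1.48 and 1.04 ± 0.0941 FPKM, and did not pass (-0.76, limma adjusted p = 0.375). Control replicate 3 stood apart in this gene too, with 1.46, 1.49 and 4.03 FPKM in control replicates 1 to 3, and without it the log2 fold change of Slc7a11 was -0.36.

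**Figure D2:**
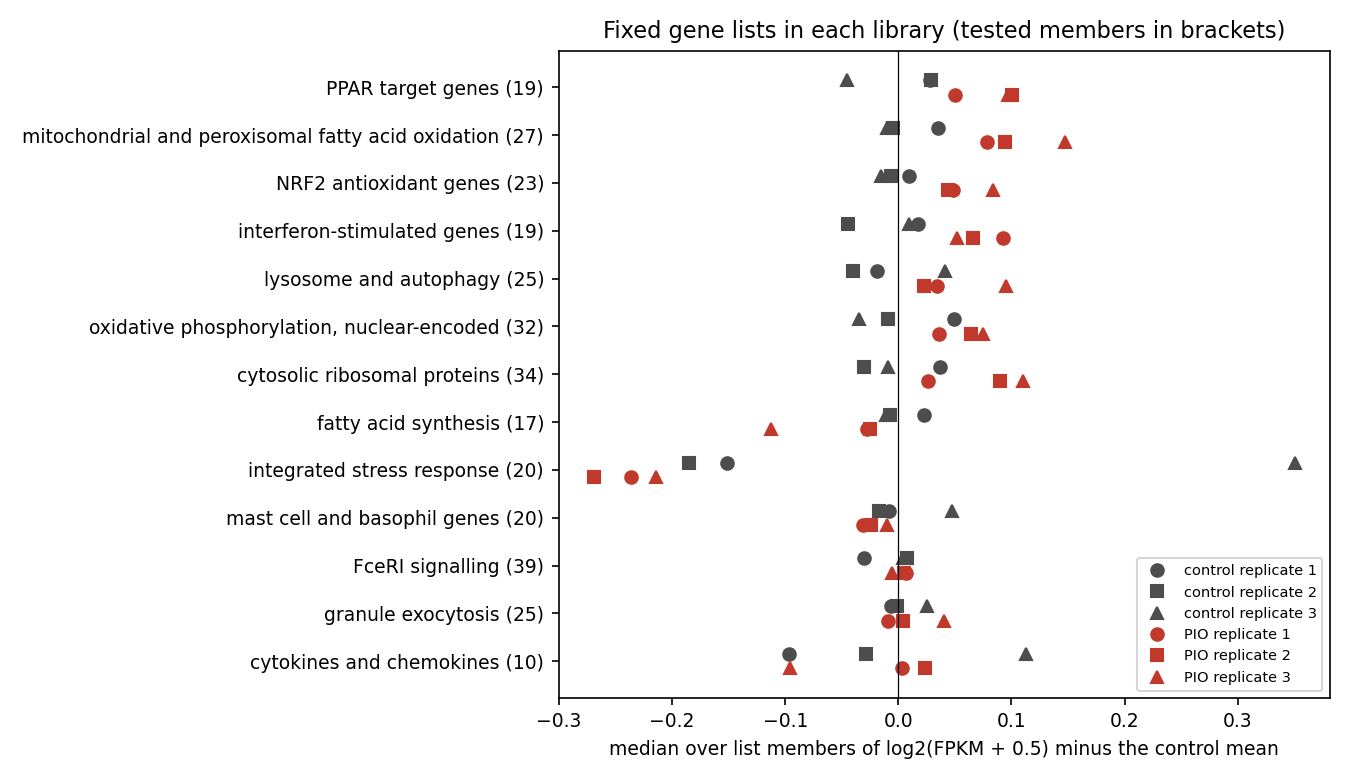
Median over the tested members of 13 gene lists of the log2(FPKM + 0.5) value minus the control mean, with 1 point per library, grey for control and red for PIO; marker shapes give the replicate number. For fatty acid oxidation the PIO libraries lie at 0.08 to 0.15 and the control libraries at -0.01 to 0.04, while for the integrated stress response control replicate 3 lies at 0.35 and the other 5 libraries between -0.27 and -0.15.

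Integrated stress response genes, which respond to amino acid shortage and to other stresses through Atf4, were lower as a list, with all 20 tested members lower and a median log2 fold change of -0.25 (camera adjusted p = 5.73e-06; adjusted p = 0.784 with an estimated correlation). No member passed, including adjusted over the list alone. The estimated correlation between members was 0.87, so their common direction is not independent evidence. Control replicate 3 stood apart in this list: Atf4 was at 279, 277 and 617 FPKM in control replicates 1 to 3 and at 243, 240 and 255 FPKM with PIO (log2 fold change -0.56, limma adjusted p = 0.438). Without control replicate 3 the list's median was -0.045 (camera adjusted p = 0.00507), and with sample weights it was -0.14 (camera adjusted p = 0.00118). Fry did not call the list (adjusted p = 0.53). Unfolded protein response genes of the endoplasmic reticulum (12 of 22 higher, median 0.01, adjusted p = 0.564), heat shock genes (13 of 15 higher, 0.04, 0.235), p53 targets (7 of 15 higher, -0.0042, 0.745) and circadian clock genes (7 of 14 higher, -0.0034, 0.753) were not called by camera. No member of these 4 lists passed, including adjusted over the list alone. The heat shock median turned to -0.013 without control replicate 3 and was 0.0093 under quantile normalization and 0.014 under TPM scaling. The medians of p53 targets and clock genes were -0.033 and -0.03 under TPM scaling. For the unfolded protein response the median was positive while the mean (-0.02) and the test were negative, and the median turned to -0.028 under quantile normalization and -0.017 under TPM scaling.

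Of 31 genes of mast cells and basophils, 20 were abundant enough to test and none of these changed over all genes tested; the other 11 could not be assessed. The IgE receptor subunit genes Fcer1a (139 ± 1.13 and 136 ± 3.39 FPKM, SD, n = 3; log2 fold change -0.03, limma adjusted p = 0.702), Ms4a2 (861 ± 7.95 and 825 ± 21.0 FPKM; -0.06, adjusted p = 0.447) and Fcer1g (562 ± 45.7 and 616 ± 26.7 FPKM; 0.14, adjusted p = 0.411) did not pass. Nor did the stem cell factor receptor gene Kit (320.3 ± 21.5 and 286 ± 20.2 FPKM; -0.16, limma adjusted p = 0.371), Gata2 (502 ± 7.58 and 512 ± 11 FPKM; 0.03, turning to -0.024 under quantile normalization and -0.0022 under TPM scaling) or the histidine decarboxylase gene Hdc (298 ± 4.56 and 296 ± 7.57 FPKM; -0.0058). Of 20 tested members 6 were higher and 14 lower (median -0.02, camera adjusted p = 0.0587). Adjusted over the list alone, the transcription factor gene Mitf fell (31.0 ± 1.48 to 26.8 ± 0.394 FPKM) and 19 members did not pass. The list was called without control replicate 2 (-0.045, adjusted p = 0.012) or PIO replicate 3 (-0.029, adjusted p = 0.045), and under TPM scaling (-0.054, adjusted p = 0.0174), quantile normalization (-0.041, adjusted p = 0.00343), median-of-ratios scaling (-0.031, adjusted p = 0.0455) and the length correction (-0.027, adjusted p = 0.0428). In the other direction, its median was -0.015 both without control replicate 3 (adjusted p = 0.359) and with sample weights (adjusted p = 0.191).

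The signalling, secretory and mediator lists were not called. FceRI signalling had 22 of 39 members higher (median 0.0099, camera adjusted p = 0.839), and no member passed, including adjusted over the list alone. Granule exocytosis had 14 of 25 higher (median 0.0095, adjusted p = 0.822); for these 2 lists the mean (-0.007 and -0.02) and the test were negative while the median was positive. With 1 library left out the FceRI median lay between 0.0038 (without control replicate 1) and 0.019 (without control replicate 3), and the exocytosis median between 0.0021 (without control replicate 2) and 0.028 (without PIO replicate 1). Adjusted over the list alone, the granule-docking GTPase gene Rab27b fell (41.7 ± 3.57 to 30.1 ± 3.24 FPKM, SD, n = 3) and 24 exocytosis members did not pass. Among 15 eicosanoid genes (9 higher, median 0.04, adjusted p = 0.736), adjusted over the list alone Ptgs1 rose, the inducible cyclooxygenase gene Ptgs2 fell (46.6 ± 4.17 to 34.9 ± 5.32 FPKM) and 13 did not pass. The eicosanoid median lay between 0.010 (without control replicate 3) and 0.068 (without PIO replicate 1) when 1 library was left out. Among 10 cytokine and chemokine genes (4 higher, median -0.07, adjusted p = 0.753), adjusted over the list alone Tgfb1 rose (196 ± 5.30 to 215 ± 5.10 FPKM) and 9 did not pass. The cytokine median was -0.01 without a filter and -0.0068 without control replicate 3, and it turned to 0.017 without PIO replicate 3. Il4 (1.49 ± 0.593 and 2.03 ± 0.662 FPKM) and Il13 (1.68 ± 0.504 and 1.55 ± 0.749 FPKM) did not pass, and Tnf had 2, 2 and 1 recovered reads in control and 0, 4 and 2 with PIO. NF-kB responsive genes (15 of 20 higher, median 0.03, adjusted p = 0.345) and immediate early genes (6 of 18 higher, -0.10, adjusted p = 0.145) were not called and no member passed, including adjusted over the list alone; the latter list was called without control replicate 2 (-0.12, adjusted p = 0.0301). Its median was -0.055 with sample weights and -0.034 without control replicate 3 (adjusted p = 0.834), the library that stood apart in the integrated stress response. Under TPM scaling the medians of FceRI signalling (-0.019), granule exocytosis (-0.02) and NF-kB responsive genes (-0.00089) turned negative, and that of eicosanoid genes did under quantile normalization (-0.012) and the length correction (-0.00071). The median of NF-kB responsive genes was 0.018 without PIO replicate 3 and 0.061 without PIO replicate 2.

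Cytosolic ribosomal protein genes were slightly higher with PIO in 34 of 34 members, with a median log2 fold change of 0.07 (camera adjusted p = 9.44e-08; adjusted p = 0.784 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were higher in 29 of 32, with a median of 0.06 (camera adjusted p = 7.25e-04; adjusted p = 0.784 with an estimated correlation). No member of either list passed, including adjusted over the list alone. The estimated correlation between members was 0.59 for ribosomal proteins and 0.33 for oxidative phosphorylation, against the preset 0.01. The members therefore vary together, and the counts of higher members are not independent evidence. The groups overlapped in both: the ribosomal protein median of control replicate 1 (0.037 above the control mean) lay above that of PIO replicate 1 (0.026), and likewise for oxidative phosphorylation (0.049 and 0.036). Examples are Rpl32 (1584 ± 24.5 and 1719 ± 74.6 FPKM, SD, n = 3) and the cytochrome c oxidase subunit gene Cox5a (317 ± 13.1 and 341 ± 9.57 FPKM). The tested members of the lists had median lengths of 717.5 and 1088 bases, against 2790 over all tested genes, and the log2 fold change fell with gene length across the 10410 genes (Spearman's rho -0.27; genes are not independent replicates). The median log2 fold change was 0.08 for the 178 genes under 500 bases and -0.05 for the 693 genes over 8000 bases. After a correction for gene length the medians were 0.012 (adjusted p = 0.0949) for ribosomal proteins and 0.019 (adjusted p = 0.315) for oxidative phosphorylation, and neither was called. Quantile normalization also ended the ribosomal protein call (0.0088, adjusted p = 0.34), fry called neither list (adjusted p = 0.307 and 0.351), and without control replicate 1 the oxidative phosphorylation median was 0.09. Under TPM scaling both calls were kept, with medians of 0.041 and 0.029. A few ribosomal protein genes were listed far below the rest, such as Rps6 (2.61 ± 0.405 and 3.94 ± 0.372 FPKM), and are uncertain because reads can be shared with processed pseudogenes.

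**Figure D3:**
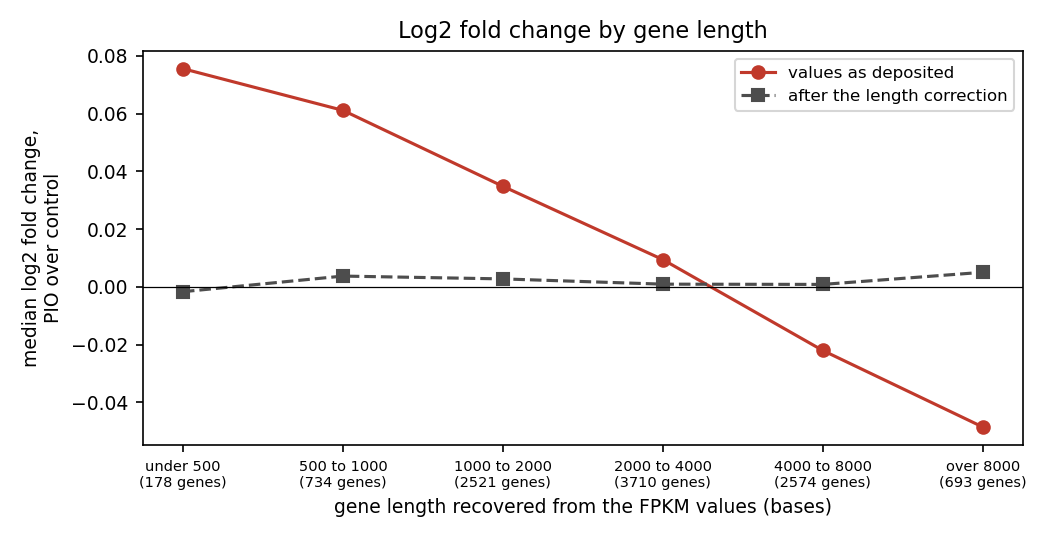
Median log2 fold change, PIO over control, of the tested genes in 6 bins of gene length in bases, for the values as deposited (red circles) and after the length correction (grey squares). The deposited values go from 0.08 in the shortest bin to -0.05 in the longest, and the corrected ones lie between -0.0017 and 0.0051.

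Interferon-stimulated genes (14 of 19 higher, median 0.09, camera adjusted p = 0.0232; adjusted p = 0.601 with an estimated correlation) and lysosome and autophagy genes (22 of 25 higher, 0.06, camera adjusted p = 0.0339; adjusted p = 0.784 with an estimated correlation) were called at the edge of the threshold. Adjusted over the list alone, the interferon regulatory factor gene Irf7 (1.92 ± 0.208 to 2.75 ± 0.131 FPKM, SD, n = 3) and the guanylate-binding protein gene Gbp2 (13.8 ± 0.181 to 16.0 ± 0.658 FPKM) rose and 17 members of the first list did not pass. In the second, adjusted over the list alone, Mitf, a regulator of lysosomal genes, fell and 24 did not pass. The interferon call was lost without control replicate 2 (0.05, adjusted p = 0.149) or PIO replicate 1 (0.09, adjusted p = 0.089). It was also lost without a filter (0.031, adjusted p = 0.0766), at a minimum mean of 1 FPKM (0.041, adjusted p = 0.0583) or 5 FPKM (0.041, adjusted p = 0.141), and by fry (adjusted p = 0.307). The lysosome call was lost without control replicate 1 (0.06, adjusted p = 0.128), control replicate 2 (0.05, adjusted p = 0.218) or PIO replicate 3 (0.028, adjusted p = 0.196), and after the length correction (0.03, adjusted p = 0.101). It was also lost under quantile normalization (0.046, adjusted p = 0.115), TPM scaling (0.034, adjusted p = 0.0644), a minimum mean of 5 FPKM (adjusted p = 0.0543), no variance trend (adjusted p = 0.0744) and fry (adjusted p = 0.471). In the lysosome list control replicate 3 (0.042 above the control mean) lay above PIO replicates 1 and 2 (0.034 and 0.022). Glycolysis and hypoxia genes were not called (23 of 28 higher, 0.04, adjusted p = 0.105). They were called without control replicate 2 (0.05, adjusted p = 0.0177) or PIO replicate 1 (0.06, adjusted p = 0.00407), and the median was 0.021 without PIO replicate 3 (adjusted p = 0.683). Under TPM scaling it was 0.0077 (adjusted p = 0.152) and under quantile normalization 0.0089 (adjusted p = 0.582). S phase genes (16 of 30 higher, 0.0046, adjusted p = 0.839) and G2 and M phase genes (17 of 30 higher, 0.0035, adjusted p = 0.839) were not called. Their medians turned negative under median-of-ratios scaling (-0.0019 and -0.0031) and TPM scaling (-0.024 and -0.025). No member of these 3 lists passed, including adjusted over the list alone.

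Across the 27 lists that could be tested, camera with a preset correlation of 0.01 called 9, of which 7 were higher and 2 lower. None of the 27 was called with an estimated correlation, and fry called 2. As a background for the counts of higher members, 5618 of all 10410 genes tested had a positive log2 fold change. The 9 other splits of the 6 libraries into 3 and 3 gave between 3 and 8 called lists and 0 changed genes each.

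No tested marker of another cell type passed. Of the lists for other blood cells and stroma, 3 of 15 macrophage and monocyte markers, 1 of 10 neutrophil, 1 of 8 eosinophil, 3 of 15 T and NK cell, 0 of 10 B cell and 2 of 14 fibroblast and adipocyte markers were abundant enough to test and these were too few for a list test. Erythroid and megakaryocyte markers were not called (4 of 7 higher, median 0.03, camera adjusted p = 0.907; -0.041 without control replicate 3 and 0.00090 under TPM scaling), and no member passed, including adjusted over the list alone. Some markers were abundant in both groups, such as the platelet factor gene Pf4 (2586 ± 111 and 2729 ± 81.2 FPKM, SD, n = 3), Nkg7 (324 ± 13.4 and 348 ± 20.7 FPKM), Thy1 (208 ± 15.6 and 212 ± 5.25 FPKM) and the myeloid transcription factor gene Spi1 (47.6 ± 0.92 and 48.5 ± 2.29 FPKM). The sign of Spi1 and Thy1 turned under TPM scaling (-0.0046 and -0.0027) and that of Pf4 after the length correction (-0.0079). Mitochondrially encoded genes were not analysed here.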

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

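Limma-voom and the length correction were chosen after seeing the data; the other settings were planned. Cpt1a passed in every setting run on genes (limma adjusted p from 5.5e-05 to 0.0208, log2 fold change 0.94 to 1.05). Of the 22 settings, the estimated correlation and fry apply to lists only. Across the settings run on genes, results for named genes were the same in 2564 cases, stronger in 10, weaker in 16 and reversed in 23. Across all 22 settings, results for lists were the same in 508 cases, stronger in 13, weaker in 37 and reversed in 36. The counts in total, higher and lower were 4, 4 and 0. Without a filter, which tests more genes, 1 gene changed (Cpt1a, 1 higher), and without a variance trend 2 did (Cpt1a and LOC100912534, 2 higher). The robust fit and limma-voom gave 7 each, with 1 lower, and 1 was lower with a pseudocount of 0.1 and with sample weights; the cause was not tested. Leaving out 1 library gave 2 to 4 higher and 0 to 2 lower, and 2 to 3 of the 4 genes were shared with the full set. Without control replicate 3, 2 were higher and 2 lower. Lists called were 0 with an estimated correlation, which widens the test, and 2 by fry, against 9. The replicate numbers gave no sign of pairing the libraries: deviations of same-numbered libraries correlated at -0.068, 0.028 and 0.078 across genes. This cannot show whether same-numbered libraries were handled together. With the replicate block 3 genes changed (Cpt1a and both placeholder genes, not Hmox1) and 9 lists were called. Depth of 14048202 to 15084729 reads limits genes near 3 reads.

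Reversed results were all uncalled in the full set, and the cause was not tested. Without a filter: granule exocytosis -0.019, immediate early genes 0.00080, p53 targets 0.0057 and clock genes 0.0034. At 5 FPKM: p53 targets 0.034. Median-of-ratios: S phase -0.0019, G2 and M phase -0.0031. Quantile: Gata2 -0.024, Hsp90ab1 -0.0026, Itgax -0.0068, eicosanoids -0.012, unfolded protein response -0.028, G2 and M phase -0.0016. TPM: Gata2 -0.0022, Spi1 -0.0046, Itgax -0.021, Thy1 -0.0027, FceRI signalling -0.019, granule exocytosis -0.020, NF-kB genes -0.00089, unfolded protein response -0.017, S phase -0.024, G2 and M phase -0.025. Sample weights: Lck 0.054, S phase -0.011, clock genes 0.027. Length correction: Pf4 -0.0079, granule exocytosis -0.0051, eicosanoids -0.00071, unfolded protein response -0.021, erythroid and megakaryocyte markers -0.0079.

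With 1 library left out, results that turned sign ranged as follows: Hdc -0.023 to 0.014, Il13 -0.41 to 0.021, Itgax -0.012 to 0.032, cholesterol biosynthesis and uptake -0.039 to 0.0075, Thy1 -0.018 to 0.086, Fabp5 -0.046 to 0.13, Lck -0.066 to 0.083, Klf1 -0.038 to 0.27, ER unfolded protein response -0.0061 to 0.020, S phase genes -0.028 to 0.038, heat shock genes -0.013 to 0.075, circadian clock genes -0.043 to 0.032, erythroid and megakaryocyte markers -0.041 to 0.098, p53 targets -0.018 to 0.0081, G2 and M phase genes -0.0041 to 0.041, Spi1 -0.0086 to 0.059 and cytokines and chemokines -0.065 to 0.017.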

Other observations

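The split counts and the read count of Pparg were chosen as tests after the results they bear on were seen; the length and Cpt1a tests and the test of single control libraries were written before their outcome, but after the patterns had been noticed.

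Pathways named in the annotation that comes with the table gave a further view. Of 288 pathways with 10 to 300 tested genes, camera called 7, all higher with PIO: ribosome, oxidative phosphorylation, Parkinson's disease, proteasome, Huntington's disease, non-alcoholic fatty liver disease and cardiac muscle contraction. The disease-named sets share many respiratory chain genes. Proteasome genes were higher in 37 of 41 members, with a median log2 fold change of 0.06 (limma camera adjusted p = 0.00165; adjusted p = 0.991 with an estimated correlation). The PPAR signaling pathway was not called: 18 of 31 members were higher, and the median was 0.028 while the test pointed down (limma camera adjusted p = 0.977). Fatty acid degradation was not called either (22 of 30 higher, median 0.07, adjusted p = 0.0564, and 0.258 after the length correction). No pathway was called with an estimated correlation, and 0 of the 7 were called after the length correction.

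The 4 changed genes were compared with other splits of the 6 libraries into 3 and 3. The real split gave 4 changed genes, the highest of the other splits gave 0, and 1 of 10 splits gave as many. For lists called by camera the real split gave 9 and the highest other 8, again 1 of 10. A total of 10 splits is too few for a share under 0.05.

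The small rises of short-gene lists were set against gene length. After each library was corrected for its trend with gene length, the ribosomal protein median went from 0.07 to 0.012 and the oxidative phosphorylation median from 0.06 to 0.019, and both calls ended because the medians shrank, which is consistent with a length trend between the groups as a candidate explanation for these lists. The trend was not the same in all libraries of a group: the correlation across genes between a library's deviation and gene length was -0.09, 0.27 and 0.22 in control and 0.12, -0.23 and -0.29 with PIO. By sign this sets control replicate 1 and PIO replicates 2 and 3 against the rest. That is the split in which 1000 genes had an unadjusted limma p under 0.05, so the length trend cuts across the groups. The fatty acid oxidation list kept its call with a median of 0.063 (limma camera adjusted p = 2.12e-05), which argues against length as its whole cause, but only at the preset correlation. Before the length correction it already lost its call with an estimated correlation (adjusted p = 0.366 with an estimated correlation). The length trend was fitted on all genes, the ribosomal and respiratory ones included, so a rise of many short genes would be partly subtracted too. An effect of PIO on ribosomal and respiratory genes stays open as untested.

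The lower integrated stress response may rest largely on 1 control library. Leaving out control replicate 3 moved the list's median from -0.25 to -0.045, while leaving out control replicate 1 or 2 gave -0.31 and -0.34. A gene length trend is argued against, since the median after the length correction was -0.27 (limma camera adjusted p = 1.32e-05). Whether control replicate 3 differed in culture or handling was not tested. Without that library the list was still called at the preset correlation (adjusted p = 0.00507). With all 6 libraries it was called neither with an estimated correlation (adjusted p = 0.784 with an estimated correlation) nor by fry (adjusted p = 0.53), so an effect of PIO on this list is left open.

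That the rise of Cpt1a belongs to a broader PPAR response is a hypothesis that the lists and the pathways leave open. The PPAR target list was called (limma camera adjusted p = 0.00581, and 0.601 with an estimated correlation). The annotated PPAR signaling pathway (18 of 31 higher, adjusted p = 0.977) and fatty acid degradation (22 of 30 higher, adjusted p = 0.0564) were not. The lists were adjusted over 27 sets and the pathways over 288, so these adjusted values are not alike. The unadjusted camera p was 0.00129 for the target list, 0.00159 for fatty acid degradation and 0.94 for the PPAR signaling pathway. Without Cpt1a the PPAR target median was 0.082 (limma camera adjusted p = 0.0445, against 0.00581 with it). The fatty acid oxidation median was then 0.078 (limma camera adjusted p = 2.43e-05). A median moves little when 1 member is taken out, so the medians cannot show how much Cpt1a contributes. At the preset correlation both lists kept a call without Cpt1a, the PPAR target list near the threshold. Both lists also hold Slc25a20, Acaa2 and Acadvl, so they are not separate evidence. Both lists lost their calls with an estimated correlation (adjusted p = 0.601 and 0.366). The well-known targets Pdk4, Fabp4, Cd36 and Angptl4 had 0 recovered reads in each PIO library, so no rise of these genes was seen. Pparg had 2 recovered reads over the 6 libraries, against 1890 for Ppard in the control libraries alone, so a route through Ppard may be considered beside one through Pparg. The read count leaves this undecided, because a receptor can act at low mRNA and because Polr2h shows that reads of an expressed gene can be missing from this table.

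The genes with placeholder symbols were compared with related named genes after their values were seen, and the comparison did not settle whether reads were shared. LOC102556337 had 62, 42 and 39 recovered reads in control and 208, 207 and 136 with PIO, and Mff, the named fission factor gene, had 207, 94 and 74 and then 106, 63 and 102. In RPM (reads scaled to the library total) the first was higher by 9.78 on average and the difference of Mff was -2.08, which rests on control replicate 1 (13.8, 6.70 and 5.03 RPM in control and 7.58, 4.42 and 7.28 with PIO). LOC100912534 had 29, 37 and 29 recovered reads in control and 112, 100 and 121 with PIO, while Polr2h had 0 in each library. The rise of LOC100912534 therefore cannot be reads that were counted for Polr2h in control, but reads counted for neither gene are not covered.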
